A study of Mus musculus with 6 samples.

How the data were processed

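The data are 6 arrays, 3 of cells treated with saline and 3 with human LDL for 48 h, hybridized on 1 slide. Per the labels' protocols, cyanine-3 cRNA was made from 100 ng of total RNA. The deposited scanner values are intensity values on a linear scale, and per the file headers Agilent Feature Extraction subtracted the background and detrended each array without normalizing between arrays. The submitters' processing notes list Agilent Feature Extraction 10.7.3.1, R 3.4.4 and limma 3.34.9. The authors also deposited a table of log2 values for the same arrays, whose normalization method is not given in the sources used here. Set against the scanner values, its columns correlated across probes with r between 0.987 and 0.993 (probes are not independent replicates), and column medians lay between 6.67 and 6.69. Its 75th percentiles lay between 9.63 and 9.64, while those of the processed signals ran from 730.4 to 961.7, so the deposited columns were aligned between arrays, by a method that stays unknown. It served as an alternative.

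The main values were log2 of the processed signal minus the 75th percentile of each array. Control spots and spots with an outlier flag were left out, and spots of one probe were averaged on the log2 scale. A probe counted as well above background on an array if at least 50% of its spots were, and it was tested if this held on all 3 arrays of at least 1 group, which 32993 of 55681 probes met. Gene names came from matching unversioned RefSeq accessions to a gene table of the assembly GRCm38.p6, used for names only. Of the probes, 28331 matched, and the others kept the name in the files. The probe with the highest mean stood for a gene, giving 24225 features, 14931 of them named. Probe sequences were not used here, so signal shared between near-identical paralogs cannot be separated.

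LDL was compared with saline by limma 3.58.1 in R 4.3.3 (lmFit and eBayes, two-sided moderated test, no covariates), with Benjamini-Hochberg adjustment over all features. An exact permutation test of 3 against 3 cannot go below p = 0.1. The 20 gene lists and the test design were fixed before the data were examined. Lists were tested by camera with a preset correlation between genes of 0.01, adjusted over the 20 lists. Of the 9 lists called this way, 0 were called with an estimated correlation. Losing the call does not by itself show that the members of a list are correlated. The inflammation list lost it with an estimated correlation of -0.0315, below the preset value. The fry test called 5 lists by direction and 10 in either direction. The named genes were, by the rule, up to 8 largest rises and 8 largest falls among genes that passed with groups that did not overlap, 17 genes named in advance, and up to 4 members with the smallest p of each list described. Some genes that the rule names are not reported here. Other names were chosen after their values were seen. A group below background on all its arrays would have given only a bound, which applied to none of the named genes tested.

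On data simulated for LDL against saline, 200 of 24225 features were changed. Recovery was 56.8% at a log2 change of 1, 87.6% at 1.5, 92.4% at 2 and 98.4% at 3. Over 5 runs 36 of 874 calls were false. Noise was drawn independently for each feature and with the same spread in both groups. The real median SD was 0.189 with saline and 0.105 with LDL, so these rates may not hold for the real arrays. The alternatives were normexp with an offset of 50 and quantile normalization (on the median rather than the mean spot signal, with the median background), quantile or median scaling, the authors' values, no or a stricter background filter, the mean over probes, single probes, replicate number or slide row as a block, trended robust variances, array weights, and each array left out. Figures were drawn with matplotlib 3.10.9.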

Results

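Gene expression was measured in adult hippocampal precursor cells of the mouse, the dividing cells of the dentate gyrus that give rise to new neurons. The cells came from male C57BL6/JRj mice 8 weeks old and were grown as an attached layer with 20 ng/ml each of the mitogens EGF and bFGF. Cultures received human LDL, the low-density lipoprotein that carries cholesterol in blood, or saline for 48 h. Per the treatment protocol in the labels the dose was 100 ug/ml, while the sample descriptions write the unit of volume differently, so the dose unit is uncertain by the labels themselves. There were 3 saline and 3 LDL arrays, from independent experiments on different passages. Each array was a 1-colour Agilent array, and the number of arrays limits the precision. Between 55.9% and 66.9% of the 55681 probes were well above background on an array, with the lowest share on saline replicate 2 and the highest on saline replicate 3.

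The comparison asks which transcripts differ after LDL, in a series whose title names cholesterol metabolism and neurogenesis. Of 25 genes on a list of sterol synthesis, 15 fell after LDL and 10 did not pass over all genes. As a list they were lower by camera (adjusted p = 7.21e-52), a call lost with an estimated correlation (adjusted p = 0.082). Of 24225 features tested, 29 passed an adjusted p of 0.05 in limma, 3 of them higher and 26 lower after LDL. The 29 comprised 21 named genes and 8 transcripts without a name in the gene table used. Fdps, the farnesyl diphosphate synthase of the mevalonate pathway, had 4.83 ± 0.09 with saline and 2.87 ± 0.11 with LDL (normalized log2 signal relative to the 75th percentile of the array, mean ± SD, n = 3 each). Its log2 fold change was -1.96 (SE 0.11, 95% interval -2.21 to -1.71, adjusted p = 0.00496), a 3.89-fold difference. Among the largest falls of named genes that passed were Hmgcs1 at -2.15, Idi1 at -2.10, Insig1 at -2.02, Msmo1 at -1.92, Cyp51 at -1.81 and Tm7sf2 at -1.79. These are enzymes of sterol synthesis except Insig1, which retains the sterol sensor complex in the endoplasmic reticulum. Only 2 named genes passed in the rising direction. Syt13, a member of the synaptotagmin family, went from -3.47 ± 0.69 to -0.15 ± 0.34, a log2 fold change of 3.32 (SE 0.35, adjusted p = 0.0346). Gfap, an intermediate filament gene of astrocytes and of radial glia-like cells, went from -3.45 ± 0.18 to -2.10 ± 0.13, a log2 fold change of 1.35 (SE 0.13, adjusted p = 0.0225). The 2 Gfap probes disagreed, since the dimmer one had a log2 fold change of 0.15, and with the mean of both the value was 0.75 and did not pass (adjusted p = 0.312, in a range up to 0.771 over the settings). Across all features tested, 14.6% of features had groups that did not overlap, against 10% by chance for 3 arrays against 3, and 1807 features had an unadjusted p below 0.05. The count of calls depended on single arrays, while the fold changes of Fdps and Hmgcs1 moved little. Without saline replicate 3, LDL replicate 2 or LDL replicate 3, 0 features passed. There were 3 without saline replicate 2, 16 without LDL replicate 1, and 29 without saline replicate 1 (6 higher and 23 lower), 20 of which were among the 29 above. With 1 array left out, the log2 fold change of Fdps stayed between -2.02 and -1.92 and that of Hmgcs1 between -2.29 and -2.03. That of Syt13 ran from 3.09 to 3.71, and Syt13 passed in limma in 10 of 18 settings (adjusted p up to 0.607). With slide row as a block 0 were higher and 14 lower. With replicate number as a block 2 were higher and 1 lower, although 1975 features then had an unadjusted p below 0.05. That block leaves the test fewer degrees of freedom. Without the background filter 0 passed. Scaling each array to its median gave 8 higher and 28 lower, and the authors' processed values gave 7 higher and 27 lower.

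The list of cholesterol synthesis enzymes and other SREBP2-controlled genes was lower after LDL, with a median log2 fold change of -1.32 over its 25 members. All 25 had a negative value, 23 had groups that did not overlap, 15 passed over all genes and 23 passed when adjusted over the list alone. The camera test against all other genes gave an adjusted p of 7.21e-52, with adjusted p = 0.082 with an estimated correlation. Hmgcs1, which makes HMG-CoA at the start of the pathway, went from 5.79 ± 0.12 to 3.65 ± 0.26, a fall of 4.43-fold (adjusted p = 0.0106), and its dimmer probe had a log2 fold change of -1.26. Sqle at -1.03 (adjusted p = 0.0984) and Srebf2 at -0.85 (adjusted p = 0.494) did not pass over all genes. Within slide row 1, with 2 arrays of each group, the list median was -1.25, and in slide row 2, with 1 of each, -1.58.

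**Figure D1:**
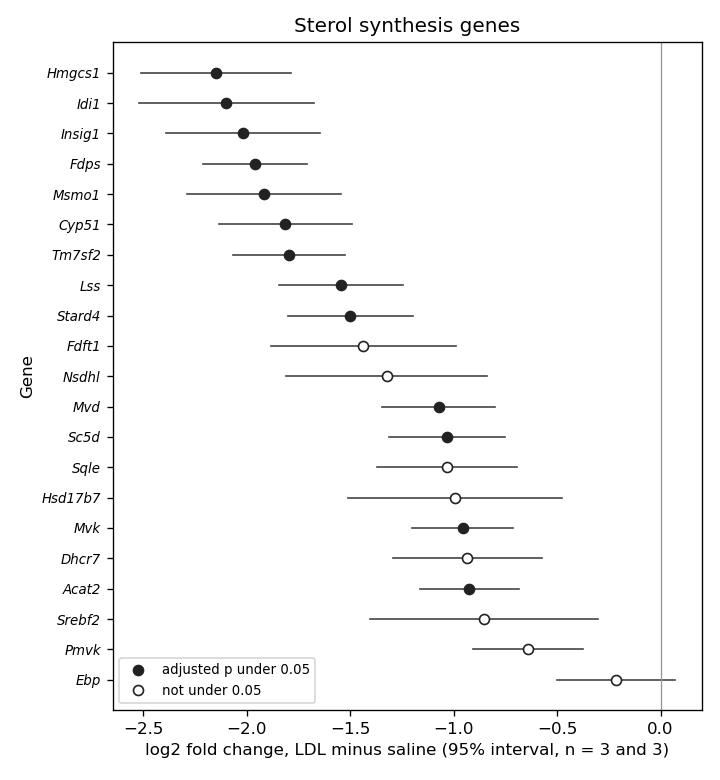
Log2 fold change (LDL minus saline, x axis) of 21 genes of the sterol synthesis list (y axis), with 95% intervals from 3 arrays per group. Filled points passed an adjusted p of 0.05 over all genes, and values run from -2.15 for Hmgcs1 to -0.22 for Ebp.

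The lipogenesis list, genes of fatty acid synthesis, elongation and desaturation, was also lower, with a median of -0.54 over 19 measured members. Of these, 3 passed over all genes, all falling, and 15 passed when adjusted over the list alone, 13 falling and 2 rising. Camera gave an adjusted p of 3.2e-12, and adjusted p = 0.0887 with an estimated correlation. Scd1, a stearoyl-CoA desaturase, fell by 1.53 (adjusted p = 0.0346), Srebf1, the transcription factor of lipogenesis, by 1.32 (adjusted p = 0.0346), and Elovl6, a fatty acid elongase, by 1.19 (adjusted p = 0.0155). Fasn had -0.85 (adjusted p = 0.0706).

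Genes of cholesterol efflux and other liver X receptor targets did not shift as a list. The median over 14 measured members was -0.07 (camera adjusted p = 0.111, and adjusted p = 0.351 with an estimated correlation), and -0.04 without saline replicate 3. Only Scd1 and Srebf1 passed, both over all genes and when adjusted over the list alone, and both also belong to the lipogenesis list. Abca1, the main cholesterol exporter, had a log2 fold change of 0.33 (95% interval -0.04 to 0.71, adjusted p = 0.719), which was 0.22 without saline replicate 2, and Smpdl3a 0.23 (adjusted p = 0.704). Abcg1 was not tested, because its probe was well above background on 2 arrays of each group only. The fry test of whether the members move one way on balance, which does not compare them with other genes, gave an adjusted p of 0.00826. The lipoprotein uptake list had a median of 0.07 over 16 members but a mean of -0.03 (camera adjusted p = 0.442).

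**Figure D2:**
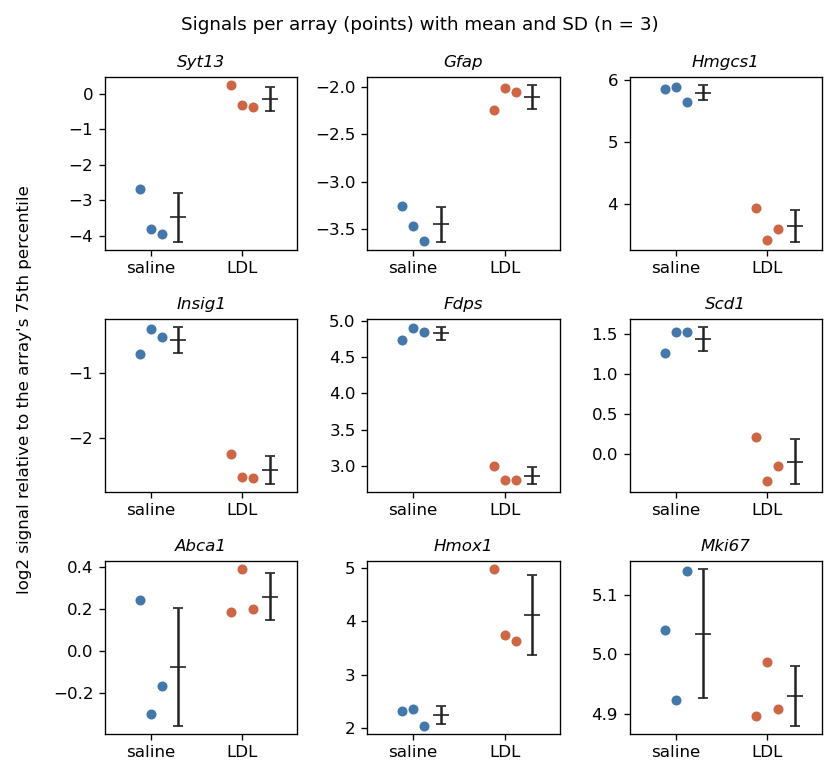
Normalized log2 signal relative to the 75th percentile of the array (y axis) of 9 genes on each of the 3 saline and 3 LDL arrays (x axis), with group mean and SD beside the points. The scales differ between panels, and the group means of Syt13 are -3.47 and -0.15 while those of Mki67 are 5.03 and 4.93.

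Genes of the oxidative stress response controlled by NRF2 were higher after LDL as a list. The median was 0.67 over 19 members, with 0 passing over all genes and 13 when adjusted over the list alone, all of them higher. Camera gave an adjusted p of 6.82e-14, and adjusted p = 0.216 with an estimated correlation. The fry test did not pass (adjusted p = 0.0829). Hmox1, heme oxygenase, had a log2 fold change of 1.88 (SE 0.35, adjusted p = 0.242). The 2 subunits of the enzyme that starts glutathione synthesis, Gclc and Gclm, had 0.99 (adjusted p = 0.243) and 1.18 (adjusted p = 0.247), and G6pdx, a source of NADPH, 1.04 (adjusted p = 0.276). Within slide row 1 the list median was 0.68 and in slide row 2 it was 0.67.

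The lysosome list, the inflammation list and the list of PPAR targets and fatty acid use were higher by smaller amounts. Lysosomal genes had a median of 0.26, with 20 of 21 positive (camera adjusted p = 3.12e-08, adjusted p = 0.239 with an estimated correlation), and fry did not pass (adjusted p = 0.147). Without saline replicate 1 the median was 0.14 (adjusted p = 9.97e-05, in a range up to 0.239 over the settings). None passed alone, over all genes or adjusted over the list alone, and Neu1 at 0.45, Ctsd at 0.43 and Ctsl at 0.35 were among the members with the smallest p. Inflammation genes had a median of 0.26 over 13 measured members of 24 (camera adjusted p = 0.000209, adjusted p = 0.0887 with an estimated correlation), with 0 passing over all genes and 3 when adjusted over the list alone. The median was 0.14 without saline replicate 3 and 0.18 without LDL replicate 1, and the camera call held in both. Those 3 were the chemokine genes Ccl7 at 0.60, Ccl2 at 0.52 and Cxcl10. The value of Ccl7 went down to 0.30 over the settings, against 0.56 at the lowest with 1 array left out. Of the 13 measured members 11 were positive, while Ccl5 at -0.53 and Nfkbia at -0.27 were negative. Il1b, Il6, Cxcl1, Icam1, Ptgs2 and Saa3 were not tested, being well above background on no array. The size of the Cxcl10 difference is uncertain, because its probe was well above background on 1 of 3 saline arrays and its log2 fold change was 1.30 here but 0.41 with normexp and quantile normalization. The PPAR list had a median of 0.10 over 26 members (camera adjusted p = 0.000239, adjusted p = 0.131 with an estimated correlation), with 0 passing over all genes and 2 when adjusted over the list alone. There were 20 positive and 6 negative values, with groups that did not overlap for 9 of the positive and 3 of the negative members. Cpt1a, which admits fatty acids to mitochondria, had 1.05 (adjusted p = 0.23), and Acadl 0.59 (adjusted p = 0.247), while Cidec, a lipid droplet gene, had -0.38 (adjusted p = 0.554). Plin2, a lipid droplet coat gene, had 0.42 (adjusted p = 0.595), and 0.28 without saline replicate 1.

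Cell cycle and DNA replication genes had a median of -0.17 over 34 members, of which 31 were negative and 0 passed over all genes or adjusted over the list alone. Camera gave an adjusted p of 5.96e-05, and adjusted p = 0.479 with an estimated correlation. Without saline replicate 2 the camera call was lost, with a median of -0.14 (adjusted p = 0.11), and without LDL replicate 1 the median was -0.11 (adjusted p = 0.00699), in a range up to 0.479 over the settings. Cdc20 had -0.33, Rrm2 -0.35 and Ccnb1 -0.37, although the probes of Ccnb1 disagreed, with values from -0.37 to -0.04, while Ccnd1, the cyclin of early G1, had 0.52 (adjusted p between 0.523 and 0.591 for the 4). Mki67, a marker of dividing cells, had -0.10 (95% interval -0.34 to 0.13), and from -0.16 without saline replicate 2 to -0.05 without saline replicate 3.

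None of the cell type lists passed camera. The medians were -0.10 for precursor markers, -0.12 for neuronal markers, -0.20 for astrocyte markers, -0.04 for oligodendrocyte markers, -0.11 for microglia markers and -0.09 for vascular markers, with adjusted p between 0.245 and 0.971. These medians are small and moved with single arrays: without LDL replicate 1 they were -0.05 for precursor, -0.07 for astrocyte and -0.02 for vascular markers, without LDL replicate 3 -0.04 for neuronal markers, and without saline replicate 3 -0.06 for microglia markers, while that of oligodendrocyte markers changed sign without LDL replicate 1 or 3. The fry test of changes in either direction, which does not compare a list with other genes, passed for precursor (adjusted p = 0.0403), neuronal (adjusted p = 0.0118) and astrocyte markers (adjusted p = 0.00017), and not for the other 3. Gfap was the only gene in these lists that passed over all genes, and its 2 probes disagreed. The other 14 measured astrocyte markers did not pass, also when adjusted over the list alone. How far the fry result of the astrocyte list rests on Gfap was not tested. Nes, an intermediate filament of precursor cells, had 0.22 (95% interval -0.24 to 0.68). This value ranged from 0.05 without LDL replicate 1 to 0.36 without saline replicate 1. Replicates 1 to 3 had Nes values of 5.297, 4.909 and 4.817 with saline and 5.565, 5.102 and 5.011 with LDL. The order was the same in both groups, so leaving out 1 array shifts the difference. Pairing by replicate number would give such a shared order, and the interval and range for Nes do not account for pairing. For Mki67 the order differed between the groups. Dcx, a marker of young neurons, was not well above background on any array. Of 16 microglia markers 8 did not meet the background filter, and likewise 8 of 16 vascular markers, so these lists rest on few genes.

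**Figure D3:**
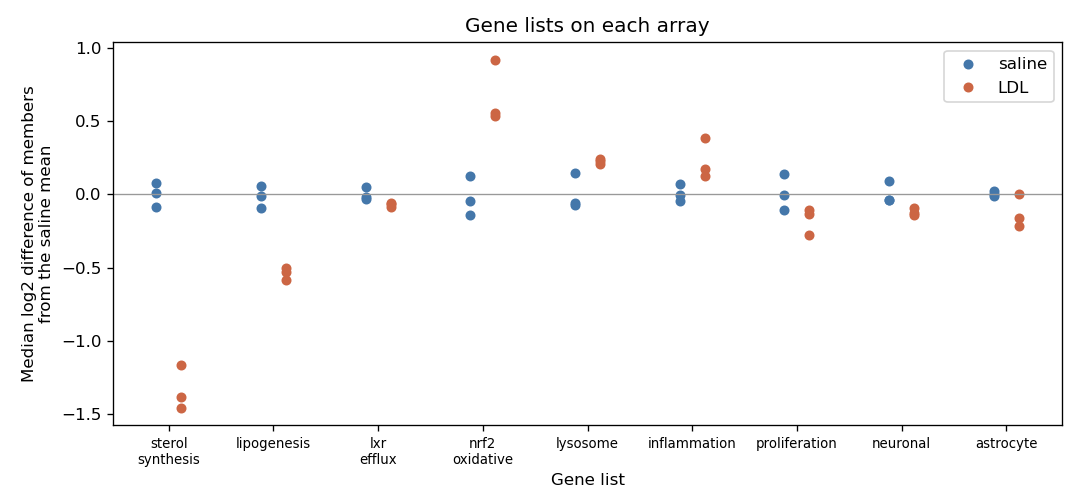
Median over list members of the log2 difference from the saline mean (y axis) for 9 gene lists (x axis) on each array. For sterol synthesis the 3 LDL arrays lie between -1.45 and -1.16 and the saline arrays between -0.08 and 0.08.

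The unfolded protein and integrated stress response list had a median of 0.03 (camera adjusted p = 0.0317, adjusted p = 0.479 with an estimated correlation), with 0 of 20 passing. Its smallest p belonged to Trib3 at 0.85, Xbp1 at 0.31, Ddit3 at 0.82 and Creld2 at 0.14, and none of them passed. Without LDL replicate 1 Ddit3 had 0.43, and without saline replicate 3 Creld2 had 0.08. Its median turned to -0.00979 without saline replicate 3 (adjusted p = 0.301), and the call was lost without saline replicate 1 (adjusted p = 0.349) and without LDL replicate 1 (adjusted p = 0.059), while the median was 0.13 without saline replicate 2 (adjusted p = 0.000522), in a range up to 0.5 over the settings. Immediate early genes had a median of -0.14 (camera adjusted p = 0.0483, adjusted p = 0.479 with an estimated correlation), and Egr2 at -0.82 was the only 1 of 16 to pass when adjusted over the list alone, with 0 over all genes. Egr1 had -0.47, Fos 0.60 and Spry2 -0.45, the last with -0.27 without LDL replicate 2. This call was lost in 15 of 20 settings, including those without saline replicate 1 (median -0.07), saline replicate 2, LDL replicate 2 (median -0.09) or LDL replicate 3, and the median was -0.27 without LDL replicate 1. The p53 and apoptosis list at 0.10, the hypoxia and glycolysis list at 0.12 and the BMP and TGF-beta list at -0.02 did not pass (adjusted p = 0.0563, 0.0563 and 0.442), though the p53 list passed in 9 of 20 settings and the hypoxia list in 7. With 1 array left out their medians ranged from 0.06 to 0.19, from 0.03 to 0.18 and from -0.10 to -0.02.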

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

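The arrays of slide row 1 alone were added as a setting after the data were seen. The 29 features that passed had the same direction in each setting that kept 1 value per gene. Both blocks and the trended robust variances leave the fold changes as they are, so direction could not change there. The count of 3 higher became 8 with normexp and quantile normalization, 5 with quantile normalization, 8 with median scaling, 7 with the authors' values, 5 with probes above background on all 6 arrays and 16 with trended robust variances, and it was 0 without the background filter, 0 with slide row as a block and 0 in slide row 1. The count of 26 lower became 14 with slide row as a block, 0 without the filter and 0 in slide row 1. Array weights gave 2312 higher and 2635 lower, but the weight estimate stopped before it converged and gave saline replicate 3 a weight of 6.58 and saline replicate 2 a weight of 0.22. Leaving out 1 array gave 0 to 6 higher and 0 to 23 lower. With 0 calls in limma, 1773 features had an unadjusted p below 0.05 without the filter, 862 in slide row 1, 1554 without saline replicate 3, 991 without LDL replicate 2 and 1375 without LDL replicate 3. In these fits with fewer arrays the test has fewer degrees of freedom. For the other settings the cause was not tested.

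With the replicate block, 2 were higher and 1 lower, and 2 of these 3 were among the 29. Each number has a saline and an LDL array, so the block leaves every fold change and the sterol synthesis median of -1.32 unchanged. Deviations of same-numbered arrays correlated across genes at 0.22, -0.04 and 0.18. Other saline-LDL pairs ran from -0.23 to 0.08. In both groups, arrays 1 and 3 correlated best with their own number but arrays 2 did not, so pairing was not assumed. Pairing is not excluded, and fits without the block would not account for it.

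The sterol synthesis list kept a negative median in 20 of 20 settings and passed in 19, with -1.32 (adjusted p = 0.082) at an estimated correlation. Its median was between -1.49 and -1.21 with 1 array left out. The proliferation list, at -0.17, did not pass with an estimated correlation (adjusted p = 0.479) or with fry (adjusted p = 0.21), and ranged from -0.23 to -0.11 with 1 array left out. The efflux list, at -0.0707, passed only with fry (adjusted p = 0.00826, in a range from 0.00826 to 0.351). Changes of sign occurred in lists with medians near 0: lipoprotein uptake to -0.0639 with array weights, vascular to 0.00929 with the authors' values, BMP and TGF-beta to 0.00435 with median scaling, the stress response to -0.0282 in slide row 1 and -0.00979 without saline replicate 3, and oligodendrocyte to 0.00258 with the mean over probes, 0.0222 in slide row 1, and 0.00855 and 0.0141 without LDL replicates 1 and 3. With 1 array left out the stress response ranged from -0.00979 to 0.128 and oligodendrocyte from -0.0407 to 0.0141. The cause was not tested.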

Other observations

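The tests of symbol families, of the number of lists called, of a single array behind the NRF2 list and both tests of the spread between saline arrays were chosen after the data were seen. Features that share the letters of their symbol were tested as 236 families of at least 8 measured genes. With the preset correlation 4 passed camera, all higher after LDL: the Vps genes of vacuolar protein sorting (median log2 fold change 0.14, 29 of 35 positive, adjusted p = 0.00891), the Acot acyl-CoA thioesterases (0.16, 11 of 11, adjusted p = 0.0358), the Cyb genes (0.11, 12 of 13, adjusted p = 0.0358) and the Mrpl mitochondrial ribosomal proteins (0.07, 36 of 48, adjusted p = 0.0358). With an estimated correlation 0 passed (adjusted p = 0.969 for each of the 4).

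The 10 splits of the 6 arrays into 3 and 3 are too few for a share under 0.05. In 1 of 10, the real split, 29 features passed, and the highest count in another split was 0. The sterol synthesis median had a size of 1.32 in the real split and at most 0.65 in another (1 of 10 as large), the NRF2 list 0.67 and at most 0.48 (1 of 10), and the proliferation list 0.175 and at most 0.171 (1 of 10). Camera with the preset correlation called 9 lists in the real split and up to 5 in another (1 of 10 as many). Each of the other splits sets 2 arrays of a treatment against 1, so part of any LDL effect remains in it, and these calls do not show how many lists the test would call with no effect.

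Saline arrays differed from each other more than LDL arrays did. The median SD of a gene was 0.189 with saline and 0.105 with LDL, a ratio of 1.8. A single aberrant saline array is argued against. The smallest median difference between 2 saline arrays, 0.195, was 1.34 times the largest between 2 LDL arrays, 0.146. This cannot address 2 deviating saline arrays, because each saline pair would then include at least 1 of them. Saline replicate 3 differed from the LDL arrays by 0.131 to 0.196, replicate 2 by 0.165 to 0.200 and replicate 1 by 0.228 to 0.239. More noise in hybridization or scanning may contribute: spike-in transcripts had a saline over LDL ratio of SDs of 1.07, with a bootstrap interval from 0.82 to 2.46 over 8 spike-ins that includes both 1 and the ratio seen for genes. A further spike-in had no spread by construction and was left out after this was seen. A difference between the cultures themselves stays open and untested.

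The rise of the NRF2 list was weighed against technical sources. A bias of the scaling with signal strength is argued against, since 0 of 10000 random lists of the same size and mean expression had a median as large, and the largest was 0.19 against 0.67. A single array as the source is argued against as well, since the median stayed at 0.54 or above with each array left out. The LDL treatment itself stays open as the source, and the call is lost with an estimated correlation (adjusted p = 0.216) and with fry (adjusted p = 0.0829), in a range from 2.91e-18 to 0.216 over the settings.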
